A study of Mus musculus with 26 samples.

How the data were processed

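Polyadenylated RNA of whole lung, of monocytes sorted from lung and of CD4 T cells isolated with magnetic beads was sequenced from C57BL/6 mice with lung metastases of B16F10 melanoma cells, treated with propranolol or left untreated. Libraries were made from poly(A) RNA with a kit of the NEBNext series and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. The authors deposited whole-number counts per gene in 2 tables, one with the lung and monocyte libraries and one with the CD4 T cell libraries; the values were not normalized. Per the submitters' processing notes, the tools named were STAR 2.7.9, featureCounts and Subread 2.0.3, and the genome build was GRCm39; whether counting used strand is not given in the sources used here, so genes that overlap or have an antisense partner, and genes with near-identical copies such as ribosomal protein genes, the Gbp family and immunoglobulin genes, are uncertain in part. Both tables list 55416 genes, of which 52083 (94.0%) carry a symbol. All 26 columns matched the title of a sample.

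Groups came from the treatment and cell type in the labels. In each comparison only the libraries of its 2 groups entered the fit: 5 against 5 for whole lung and 4 against 4 for the others. Genes were kept by the default filterByExpr rule (minimum count 10), libraries were scaled by TMM, and each gene was tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are propranolol over control with standard errors (SE), and CPM given as mean ± SD are TMM-scaled unless called plain or given for the untreated groups alone. Between kinds of material, the difference of the log2 changes was tested as an interaction in 1 fit with 4 groups. The number of genes expected in both of 2 independent lists of calls was computed per direction from each list's size among the genes tested in both.

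Before the data were examined, 45 lists of cell type markers and pathways were fixed together with the tests, the alternatives and the rule for the genes named in the text. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, against all other tested genes; the adjusted p with an estimated correlation is given beside it. The rule named, per comparison, up to 30 genes: the 6 genes with the smallest p in each direction among called genes with a mean of at least 1 CPM, leaving out predicted loci and immunoglobulin or T cell receptor segments; the β-adrenoceptor genes, and in lung also Tyrp1, Dct, Pmel and Mlana; then called members of lists in the order of their p. Some genes that the rule named are not reported here.

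Alternatives were the size factors of DESeq2 1.42.0, its own test, limma-voom without and with quality weights, no filter and a stricter one (mean of at least 5 CPM), the replicate number as a block, each library left out in turn, lung and monocyte libraries in 1 fit, the mean level of the melanocyte list as a covariate in lung, and for lists fry and the estimated correlation. Scaling on resident lung cell markers, summing the close monocyte libraries and leaving libraries out of the interaction fits were chosen after the data had been seen. In the interaction fit with resident scaling only the lung libraries were scaled on those markers, and the monocyte libraries by TMM among themselves. The scripts were tested on simulated counts drawn from the real means and library sizes. In the whole lung simulation, with 18325 genes tested, 36.9% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 95.2% of those changed 4-fold were recovered, and 0.758% of the calls were false. For the monocyte design (17950 genes tested) the shares were 64.6%, 76.9% and 98.5%, with 6.59% false. For the CD4 T cell design (16125 genes tested) they were 42.2%, 68.2% and 93.4%, with 7.53% false. In every design only 61 to 67 of the tested genes were altered singly at each fold change, besides a small set of genes raised 1.5-fold together. In the data 70.8% of tested genes changed in lung, 30.5% in the monocyte libraries and 60.0% in the CD4 T cell libraries. The simulated shares apply to such sparse changes. Recovery and false calls with changes as widespread as in the data were not tested. Replicate libraries of a group were compared by chi-square over genes with a mean count of at least 50. No pair agreed within sampling noise, and each library was counted as 1 sample. Repeat libraries of 1 sample can also differ by more than sampling noise, so this check does not show that the libraries were separate samples.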

Results

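The series measured polyadenylated RNA in C57BL/6 mice carrying lung metastases of B16F10, a mouse melanoma cell line injected into a vein. Mice received propranolol, a blocker of β-adrenoceptors, or no treatment. The 3 kinds of material sequenced were whole lung, monocytes isolated from lung by flow sorting, and CD4 T cells isolated with magnetic beads. Each treatment had 5 whole lung libraries, 4 monocyte libraries and 4 CD4 T cell libraries, 26 in all. Total counts per library ran from 33232082 to 47618634 in untreated and from 29650148 to 43447855 in treated lung. In the monocyte libraries they ran from 36371431 to 48306925 and from 36277687 to 46407803, and in the CD4 T cell libraries from 17625672 to 35600275 and from 27742422 to 42484125. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries. Gene positions are not given, because no annotation of the genome build of the counts was used here.

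The untreated libraries showed what each kind of material held, in CPM, a gene's count scaled to a fixed library total. Melanocyte transcripts were abundant in whole lung, with Tyrp1, a pigment enzyme, at 4601 ± 794 CPM and Dct, another pigment enzyme, at 5299 ± 670 CPM (SD, n = 5). The libraries labelled monocytes held the monocyte genes Csf1r at 457 ± 49.4 CPM, Cd14 at 673 ± 69.5 CPM and Ccr2 at 94.1 ± 9.06 CPM (SD, n = 4). In whole lung these stood at 84.3 ± 26.2, 20.6 ± 7.05 and 19.2 ± 4.05 CPM (SD, n = 5). The libraries labelled monocytes also held transcripts of other cells. Sftpc of alveolar type 2 cells stood at 2300 ± 95.7 CPM, Scgb1a1 of club cells at 3838 ± 702 CPM and Cdh5 of endothelium at 1679 ± 51.2 CPM. Col1a1 of fibroblasts stood at 592 ± 33.6 CPM and Tyrp1 at 1029 ± 64.6 CPM. Relative to the mean of untreated whole lung, Cdh5 stood at a ratio of 3.51, not far below Ccr2 (4.91) and Csf1r (5.43). Cd14 stood at 32.7, whereas the ratio was below 1 for Sftpc (0.494), Scgb1a1 (0.670), Col1a1 (0.670) and Tyrp1 (0.224). These libraries are therefore called libraries labelled monocytes throughout. In the libraries labelled CD4 T cells, Cd4 stood at 644 ± 4.90 CPM and Cd3e of the T cell receptor complex at 290 ± 9.98 CPM. Cd8a of the other major T cell class stood at 4.56 ± 0.904 CPM. Igha, the heavy chain of immunoglobulin A made by plasma cells, stood at 6706 ± 140 CPM (SD, n = 4).

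**Figure D1:**
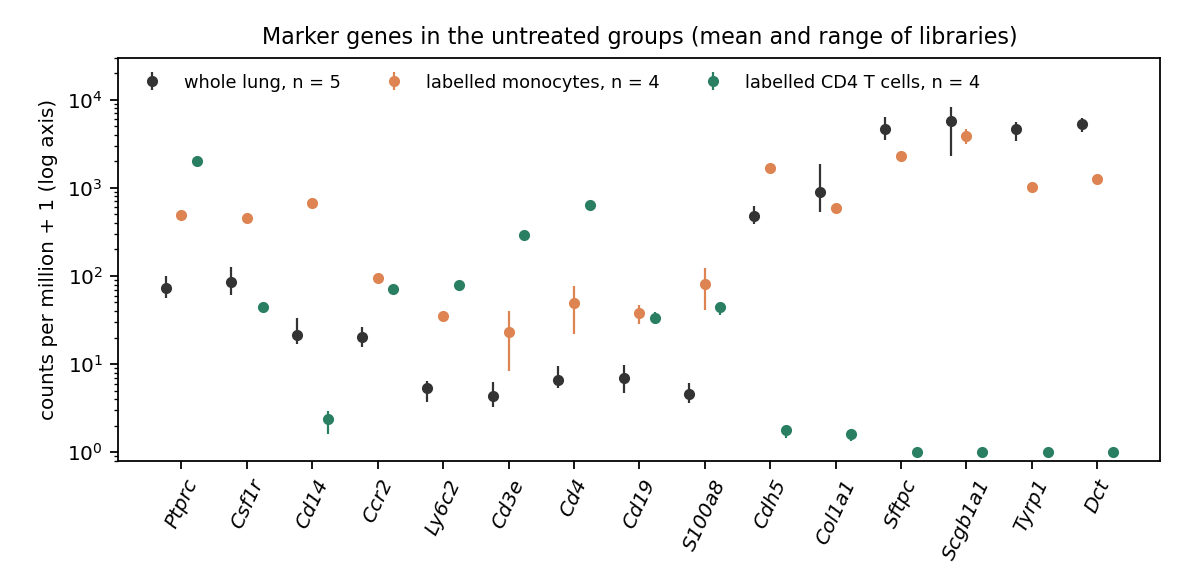
CPM plus 1, on a log axis, of marker genes in the untreated groups. Points are means and bars span the lowest to the highest library. Cdh5, Col1a1, Sftpc, Scgb1a1 and Tyrp1 are abundant in the libraries labelled monocytes as well as in whole lung. Of these, Cdh5 lies higher in the libraries labelled monocytes than in whole lung.

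The first comparison asked how whole lungs with metastases differed between propranolol and no treatment. Treated lungs held less RNA of melanocyte, dividing-cell and glycolysis genes and more RNA of B cell, T cell and antigen presentation genes. Each of these lists passed with the preset correlation and not with an estimated one (adjusted p = 0.505). Tyrp1 (ENSMUSG00000005994) fell from 4927 ± 959 to 991 ± 732 CPM (SD, n = 5 each, scaled libraries), a log2 change of −2.31 ± 0.50 (SE, adjusted p = 0.00194). In the opposite direction, Ighd, the heavy chain of immunoglobulin D on naive B cells, rose from 8.98 ± 1.55 to 38.5 ± 5.85 CPM, a log2 change of 2.10 ± 0.14 (SE, adjusted p = 2.7e-05). Of 18639 genes tested, 13189 (70.8%) changed, 6614 of them higher and 6575 lower with propranolol. By more than 2-fold, 3181 rose and 1571 fell.

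All 15 measured genes of the melanocyte list were lower, with a median log2 change of −2.05. Dct changed by −1.97 ± 0.54 log2, Pmel, a protein of pigment granules, by −2.21 ± 0.51 and Mlana by −1.93 ± 0.49 (SE, adjusted p = 0.00681, 0.00262 and 0.00446). Treated lungs differed widely in these transcripts. Plain CPM of Tyrp1 ran from 231 to 2034 among the 5 treated libraries and from 3430 to 5601 among the 5 untreated ones. The cell cycle list fell in 30 of 30 members (median −1.57). Mcm6, part of the replicative helicase, fell by 1.33 ± 0.23 log2 and Pcna, the sliding clamp of DNA polymerase, fell by 1.14 ± 0.20 (SE). The hypoxia and glycolysis list had 18 of 22 members lower and 3 higher, with a median of −1.99. Nuclear genes of oxidative phosphorylation fell in 25 of 25 members. Cox6c of complex IV fell by 0.91 ± 0.11 log2 and Ndufs6 of complex I fell by 0.92 ± 0.11 (SE). Cytosolic ribosomal protein genes fell in 32 of 32 members (median −0.65), with Rpl23 at −0.76 ± 0.10 log2 (SE). In cholesterol synthesis, 18 of 19 genes fell (median −0.86).

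The B cell list rose in all 17 measured members, with a median log2 change of 1.84. Siglecg, an inhibitory receptor of B cells, rose from 2.89 ± 0.539 to 17.5 ± 2.98 CPM, and Cr2, a complement receptor of B cells, from 2.32 ± 0.177 to 10.7 ± 1.71 CPM (SD, n = 5 each). Cd37, a tetraspanin of leukocytes, rose by 1.66 ± 0.11 log2 (SE). The T cell list rose in 21 of 21 members (median 1.46), with Cd2 up by 1.12 ± 0.14 log2 (SE). The cytotoxic lymphocyte list rose in 17 of 18 members (18 when adjusted over the list alone; median 1.53) and the MHC class II list in 10 of 10 (median 1.30). Ciita, the master activator of class II genes, rose by 1.54 ± 0.14 log2 and H2-Ob by 2.10 ± 0.19 (SE). The platelet and megakaryocyte list had 9 of 10 members higher (median 1.97), and the neutrophil list 8 of 14 higher and 1 lower (median 1.52). Of MHC class I genes 15 of 18 were higher (median 0.78), and of interferon-γ response genes 20 of 24 were higher and 1 lower (median 0.87). Classical monocyte genes were higher in 13 of 17 (median 0.80), and dendritic cell genes were higher in 11 of 16 and lower in 1 (median 0.83). Counts adjusted over the list alone were identical for these lists, the cytotoxic one apart.

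Genes of resident lung cells were also higher in the scaled counts of treated lungs. This held for 16 of 17 genes of endothelium (median 0.77), 12 of 13 of alveolar type 1 cells (median 0.77) and 13 of 14 of alveolar type 2 cells (median 0.69). It also held for 9 of 12 genes of smooth muscle and pericytes (median 0.78) and 12 of 17 of alveolar macrophages, with 1 lower (median 0.57), although the alveolar macrophage median was −0.19 when libraries were scaled on markers of the other resident cells. The lists of non-classical monocytes (12 higher and 3 lower of 17) and of type I interferon response (11 higher and 2 lower of 30, 10 and 2 when adjusted over the list alone) did not pass the test (adjusted p = 0.0612 and 0.0928). Neither did those of fibroblast and extracellular matrix (4 higher and 10 lower of 20) or of airway epithelium (8 higher and 4 lower of 14). Signalling lists that did not pass were circadian clock (10 higher and 4 lower of 16), cAMP and CREB targets (4 higher and 7 lower of 19) and immediate early genes (6 higher and 6 lower of 19, 6 and 5 when adjusted over the list alone). Among lists of macrophage state, inflammatory cytokines (5 higher and 4 lower of 20), alternative activation (9 higher and 4 lower of 16) and interstitial macrophage (3 higher and 7 lower of 19) did not pass. The same was true of cardiac muscle (6 of 12 lower, 4 when adjusted over the list alone), adipocyte (1 of 6 higher) and erythroid genes (1 of 9 lower). The median and mean log2 changes differed in sign for airway epithelium (0.70 and −0.63), interstitial macrophage (0.13 and −0.33) and alternative activation (0.48 and −0.10). The inflammatory list had a negative median (−0.14) with an upward test direction. The mitochondrially encoded genes were listed at 0 in every library.

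The smallest p-values among higher genes, besides Siglecg, Cr2 and Cd37, belonged to Neat1, a nuclear long noncoding RNA (1.97 ± 0.12 log2), Leng8 (1.96 ± 0.13) and Trim30b (2.59 ± 0.18; SE, adjusted p = 2.7e-05 for each). Those among lower genes belonged to the chaperone genes Hsph1 (−1.77 ± 0.14) and Dnaja1 (−0.93 ± 0.08) and to Ddit4, a stress-induced inhibitor of mTOR signalling (−1.46 ± 0.13; SE). Tmem56 (−1.46 ± 0.13), the fatty acid transporter gene Slc27a4 (−0.72 ± 0.06) and Smpd1, acid sphingomyelinase (−1.22 ± 0.11; SE), were lower too. Adrb1 and Adrb3, which encode β-adrenoceptors, were higher. Adrb1 stood at 29.9 ± 14.2 in untreated and 66.4 ± 12.6 CPM in treated lung (SD, n = 5 each; adjusted p = 0.0104). Adrb3 rose by 1.66 ± 0.39 log2 (SE, adjusted p = 0.00290). With the melanocyte level of each library as a covariate their log2 changes were 0.59 and 0.57 (adjusted p = 0.485 and 0.496).

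**Figure D2:**
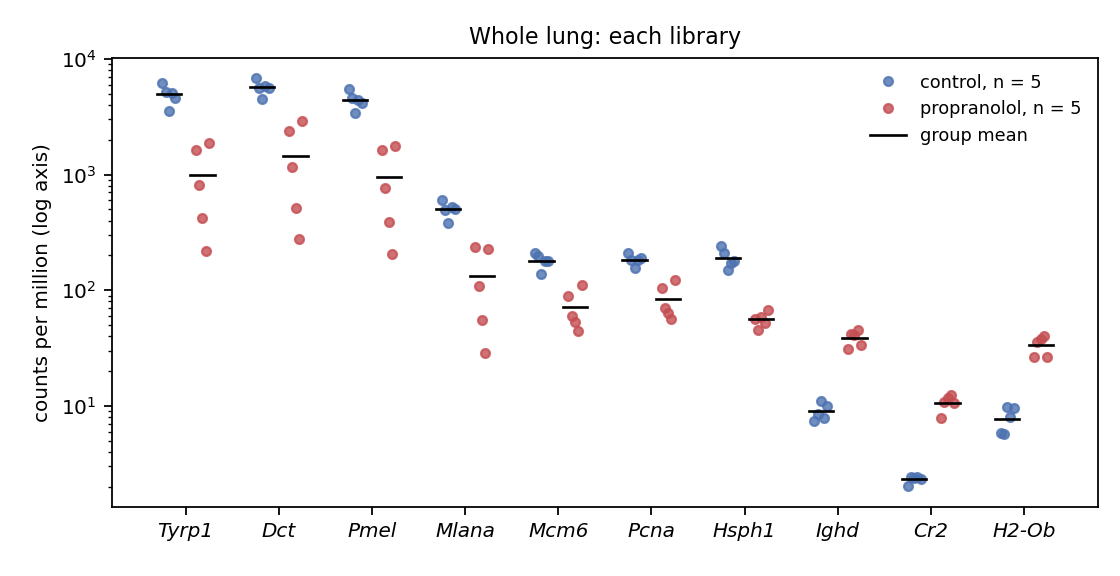
CPM (log axis, scaled libraries) of 10 genes in each whole lung library, with black bars at the group means. Tyrp1 fell from a mean of 4927 to 991 CPM while Ighd rose from 8.98 to 38.5 CPM.

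None of the 21 lists past the threshold in whole lung (15 higher, 6 lower) passed when the correlation between a list's genes was estimated, with adjusted p = 0.505 or adjusted p = 0.543 for each of them. With the melanocyte level as a covariate 1498 genes changed, 784 higher and 714 lower, and the lists of melanocyte, cell cycle (median −0.04), alveolar macrophage, dendritic cell, alveolar type 1 and 2, endothelium and smooth muscle genes no longer passed (adjusted p from 0.0520 to 0.970), nor did Tyrp1, Dct, Pmel, Mlana, Mcm6, Pcna and Rpl23 (0.0652 to 0.787). Scaling the libraries on 56 marker genes of alveolar type 1 and 2 cells, endothelium and smooth muscle, whose medians near 0 it fixes, moved the median log2 change of all genes to −0.72, with 1829 genes higher and 10825 lower (14.5% higher, against 50.1% with TMM). Under that scaling B cell (1.09), cytotoxic (0.80), T cell (0.75), MHC class II (0.54) and platelet (1.24) medians stayed above 0. Lists were tested there with fry, which asks whether a list moves on balance and not whether it differs from other genes. With fry, MHC class I (median 0.02, adjusted p = 0.677), interferon-γ response (0.11, adjusted p = 0.463), neutrophil (0.76, adjusted p = 0.109), classical monocyte (0.05, adjusted p = 0.203) and dendritic cell genes (0.07, adjusted p = 0.122) passed under TMM and not under that scaling. The type I interferon list turned to 1 higher and 17 lower of 30 (median −0.45, adjusted p = 0.0103 with fry). Fibroblast and extracellular matrix genes were lower in 17 of 20 (−1.43, adjusted p = 0.0103), cAMP and CREB targets in 15 of 19 (−0.88, adjusted p = 0.00173) and immediate early genes in 13 of 19 (−0.80, adjusted p = 0.00295), with none higher. Interstitial macrophage genes were lower in 10 of 19 with none higher (−0.58, adjusted p = 0.0238), and inflammatory cytokine genes in 8 of 20 with 1 higher (−0.93, adjusted p = 0.0205). Adrb1 did not pass under it (log2 0.46, adjusted p = 0.150).

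The second comparison asked how the libraries labelled monocytes differed between propranolol and no treatment. Genes of cytotoxic lymphocytes and B cells rose, and genes of fibroblasts, extracellular matrix and endothelium fell. With an estimated correlation the B cell list did not pass (adjusted p = 0.109). Prf1, the pore-forming protein of cytotoxic cells, rose from 4.05 ± 0.199 to 18.5 ± 3.31 CPM (SD, n = 4 each), a log2 change of 2.19 ± 0.13, and Postn, a matrix protein, fell by 0.92 ± 0.04 log2 (SE). The smallest p-value belonged to Hsph1 (ENSMUSG00000029657), a chaperone of the heat shock response, which fell from 221 ± 6.35 to 77.5 ± 0.385 CPM, a log2 change of −1.51 ± 0.04 (SE, adjusted p = 4.12e-09). Of 18236 genes tested, 5553 (30.5%) changed, 2614 higher and 2939 lower. Of these, 314 rose and 130 fell by more than 2-fold.

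The cytotoxic lymphocyte list had 15 of 17 members higher, with a median log2 change of 1.90 (adjusted p = 0.0462 with an estimated correlation). The fibroblast and extracellular matrix list had 16 of 20 members lower and 3 higher (median −0.65), and the endothelium list 16 of 17 lower (median −0.45). Both held with an estimated correlation (adjusted p = 0.00815). Within the fibroblast list Col6a2, a collagen VI chain, fell by 0.69 ± 0.04 log2, whereas Dcn, a small matrix proteoglycan, rose by 0.63 ± 0.09 and Thbs2 by 0.52 ± 0.12 (SE). In the endothelium list Ramp2, a partner of the adrenomedullin receptor, fell by 0.64 ± 0.04 log2 and Cldn5, a tight junction protein, by 0.51 ± 0.03 (SE). Melanocyte genes rose in these libraries, in 12 of 15 members (14 when adjusted over the list alone; median 0.49, adjusted p = 0.511 with an estimated correlation). Alveolar type 2 genes were lower in 8 of 14 and higher in 1 (9 and 1 when adjusted over the list alone; median −0.16, adjusted p = 0.360 with an estimated correlation).

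The B cell list had 16 of 17 members higher (17 when adjusted over the list alone; median 1.02, adjusted p = 0.109 with an estimated correlation). Ighd rose by 1.81 ± 0.11 log2 and Pax5, the B cell identity factor, by 1.18 ± 0.08 (SE). The T cell list had a median of 0.96 but 3 of 21 members called higher (2 when adjusted over the list alone; adjusted p = 0.647 with an estimated correlation). Cd3e ran from 7.45 to 39.0 plain CPM among the 4 untreated libraries. The non-classical monocyte list had 13 of 17 members higher and 2 lower (14 and 2 when adjusted over the list alone; median 0.54, adjusted p = 0.109 with an estimated correlation). The lower ones were Cd36, a scavenger receptor (−0.33 ± 0.04), and Ace (−0.25 ± 0.05; SE), which endothelium also makes. The classical monocyte list had 8 of 17 higher and 2 lower (8 and 3 when adjusted over the list alone; median 0.19, adjusted p = 0.263 with an estimated correlation). The interferon-γ response list had 16 of 25 higher (20 when adjusted over the list alone; median 0.55, adjusted p = 0.360 with an estimated correlation). Irf8, a transcription factor of myeloid cells, rose by 0.64 ± 0.06 log2 and Cd274, which encodes the checkpoint ligand PD-L1, by 0.57 ± 0.06 (SE).

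Smaller shifts past the preset test, none of which passed with an estimated correlation, were seen in 10 further lists. Cytosolic ribosomal protein genes were higher in 30 of 32 members (31 when adjusted over the list alone; median 0.32, adjusted p = 0.190 with an estimated correlation), with Rps7 up by 0.43 ± 0.03 and Rpl32 by 0.41 ± 0.03 log2 (SE). MHC class I genes were higher in 14 of 18 (median 0.28, adjusted p = 0.145), MHC class II in 5 of 10 (median 0.16, adjusted p = 0.0755) and cell cycle in 18 of 30 (median 0.32, adjusted p = 0.422), each p with an estimated correlation. Oxidative phosphorylation genes were higher in 13 of 25 (median 0.14, adjusted p = 0.603) and alveolar macrophage genes in 8 of 17 with 1 lower (median 0.27, adjusted p = 0.511), each p with an estimated correlation. Adjusted over the list alone, these counts were 16, 7, 24, 15 and 9 higher. Type I interferon genes were higher in 11 of 30 and lower in 5 (14 and 5 when adjusted over the list alone; median 0.17, adjusted p = 0.545 with an estimated correlation). Immediate early genes were lower in 6 of 19 (median −0.10, adjusted p = 0.263 with an estimated correlation). Interstitial macrophage genes were lower in 5 of 19 with 1 higher (7 and 1 when adjusted over the list alone; median −0.24, adjusted p = 0.647) and neutrophil genes in 4 of 18 (median −0.43, adjusted p = 0.648), each p with an estimated correlation. Lists of platelets, inflammatory cytokines, alternative activation, cholesterol synthesis, hypoxia, circadian clock, dendritic cells, cAMP and CREB targets, phagocytosis and lysosome, and erythroid cells did not pass, with adjusted p from 0.0836 to 0.646.

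Among single genes with the smallest p-values, Mbp (0.79 ± 0.03 log2), Cd300e, a receptor of non-classical monocytes (1.37 ± 0.06), and the kinase gene Ptk2b (0.66 ± 0.03; SE) rose. So did the chemokine gene Ccl5 (1.77 ± 0.09) and the leukocyte integrin genes Itgb7 (0.73 ± 0.04) and Itgal (0.61 ± 0.03; SE). Hspa12b (−1.05 ± 0.04), the transcription factor genes Tbx3 (−0.94 ± 0.04) and Sox13 (−1.06 ± 0.04), Pdzd2 (−0.89 ± 0.03) and Arap3 (−0.84 ± 0.03; SE) fell. Adrb1 fell from 71.8 ± 3.16 to 39.2 ± 0.582 CPM and Adrb3 from 4.76 ± 1.70 to 2.53 ± 0.411 CPM (SD, n = 4 each). Their adjusted p was 4.84e-07 and 0.0149, and in 1 fit with the lung libraries 0.0675 and 0.140.

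Within each monocyte group, libraries 1 and 2 and libraries 3 and 4 lay close together, with a chi-square per gene of 3.52 to 5.28 against 12.5 to 35.7 for the other pairs of a group. With those close libraries summed, leaving 2 against 2, 1377 genes changed (409 higher, 968 lower), and Thbs2, Cd36, Ace and Adrb3 no longer passed (adjusted p from 0.0728 to 0.192). In 1 fit with the lung libraries 2069 genes changed (819 higher, 1250 lower), and Dcn, Thbs2, Cd36, Ace, Cldn5, Rpl32 and Itgal no longer passed (adjusted p from 0.0547 to 0.482).

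The third comparison asked how the libraries labelled CD4 T cells differed between propranolol and no treatment. Immediate early genes, genes listed as cAMP and CREB targets, T cell activation genes and interferon-γ response genes rose, several of them by more than 10-fold. Whether cAMP signalling itself changed was not tested. Nr4a3 (ENSMUSG00000028341), an orphan nuclear receptor induced by receptor signalling, rose from 32.1 ± 1.84 to 4478 ± 528 CPM (SD, n = 4 each), which was 139-fold, with a log2 change of 7.12 ± 0.11 (SE, adjusted p = 3.93e-12). Crem, a transcription factor induced by cAMP, rose 83.2-fold and Nr4a1 42.4-fold. Of 16550 genes tested, 9929 (60.0%) changed, 4982 higher and 4947 lower. By more than 2-fold, 1928 rose and 2213 fell.

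The list of cAMP and CREB targets had 18 of 19 members higher and none lower, with a median log2 change of 2.94 (adjusted p = 9.11e-04 with an estimated correlation). Its members include Nr4a3, Crem, Nr4a1 (5.41 ± 0.08) and Rgs2, a regulator of G protein signalling (4.14 ± 0.07; SE). The immediate early list had all 19 members higher (median 2.28, adjusted p = 9.11e-04 with an estimated correlation) and shares 2 genes with the cAMP list. Junb rose by 3.43 ± 0.07 log2 and Klf6 by 2.28 ± 0.05 (SE). The activated T cell list had all 14 members higher (median 2.51, adjusted p = 0.00206 with an estimated correlation). Cd69, an early surface marker of activation, stood at 74.4 ± 5.89 in untreated and 849 ± 34.5 CPM in treated libraries, and Irf4 at 97.1 ± 4.41 and 1073 ± 76.1 CPM (SD, n = 4 each). The interferon-γ response list had 19 of 22 members higher and 1 lower (20 and 1 when adjusted over the list alone; median 1.77, adjusted p = 0.00102 with an estimated correlation). In it the chemokine gene Cxcl10 rose from 3.76 ± 0.477 to 215 ± 9.20 CPM and Irf1 from 176 ± 3.14 to 742 ± 12.6 CPM (SD, n = 4 each), whereas Gbp8 fell by 0.65 ± 0.20 log2 (SE).

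Lists of CD4 T cell subsets had members moving both ways. The Th2 list had 8 of 9 members higher and 1 lower (median 2.52), the Th1 list 9 of 13 higher and 1 lower (median 0.68) and the T follicular helper list 4 of 8 higher and 1 lower (median 0.54). Each passed with an estimated correlation (adjusted p = 0.0213, 0.0337 and 0.0310). The regulatory T cell list had 11 of 15 higher and 1 lower (12 and 1 when adjusted over the list alone; median 1.16, adjusted p = 0.110 with an estimated correlation). The cytokine gene Il10 rose by 4.46 ± 0.16 log2 and the checkpoint gene Ctla4 by 2.59 ± 0.10, and Nrp1 fell by 0.47 ± 0.10 (SE). The checkpoint list had 8 of 13 higher and 1 lower (median 0.60) and the Th17 list 7 of 11 higher and 1 lower, each with adjusted p = 0.0624 with an estimated correlation. The naive and quiescent list had 6 of 12 higher and 4 lower (median 0.18, adjusted p = 0.404 with an estimated correlation).

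Markers of several other kinds of cells rose in the same libraries. Igha of plasma cells was not among them, at 6706 ± 140 in untreated and 4477 ± 1203 plain CPM in treated libraries (SD, n = 4 each). The neutrophil list had all 18 members higher (median 2.44) and the B cell list 16 of 17 (median 1.84), each with adjusted p = 0.0572 with an estimated correlation. Lcn2, a granule protein of neutrophils, rose by 3.07 ± 0.11 log2 and Acod1, an enzyme of activated phagocytes, by 6.86 ± 0.24 (SE). Ighd rose by 2.15 ± 0.08 and Blk, a B cell kinase, by 2.07 ± 0.09 (SE). The myeloid list had all 15 members higher (median 1.32, adjusted p = 0.0481 with an estimated correlation). Cd14 stood at 1.21 ± 0.510 in untreated and 76.5 ± 5.90 CPM in treated libraries and Clec7a at 6.20 ± 0.805 and 50.4 ± 1.12 CPM (SD, n = 4 each). The MHC class II list had 10 of 10 higher (median 1.65, adjusted p = 0.210 with an estimated correlation). Cd4 itself, chosen after its values were seen, stood at 564 ± 4.49 and 524 ± 61.5 CPM in scaled libraries (log2 −0.11 ± 0.08, SE, adjusted p = 0.251). In plain CPM it stood at 644 ± 4.90 in untreated and 458 ± 55.5 in treated libraries (SD, n = 4 each), without overlap. The result for Cd4 thus rests on the TMM factors, which averaged 1.14 in untreated and 0.874 in treated libraries. The nuclear noncoding RNA Malat1, also chosen after its values were seen, fell from 3075 ± 221 to 790 ± 461 CPM (SD, n = 4 each).

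The cell cycle list had 17 of 30 members lower and 2 higher (median −0.58, adjusted p = 0.591 with an estimated correlation). Ribosomal protein genes were higher in 32 of 32 (median 0.53, adjusted p = 0.591 with an estimated correlation). Circadian clock genes were higher in 10 of 16 with 3 lower (median 0.82, adjusted p = 0.265 with an estimated correlation). Cholesterol synthesis genes were higher in 10 of 18 with 5 lower (median 0.52, adjusted p = 0.0754 with an estimated correlation), and hypoxia and glycolysis genes in 12 of 22 with 6 lower (median 0.52, adjusted p = 0.221 with an estimated correlation). Lists of cytotoxic lymphocytes, endothelium, melanocytes, platelets, MHC class I, type I interferon response, erythroid cells, oxidative phosphorylation and alveolar type 2 cells did not pass, with adjusted p from 0.0650 to 0.891. Further genes among the smallest p-values were Dusp5, a phosphatase that acts on ERK (4.45 ± 0.07), and Cdkn1a, which encodes the cell cycle inhibitor p21 (5.51 ± 0.09; SE), both higher. Lower were Arhgap9 (−1.83 ± 0.05), Fam78a (−1.78 ± 0.05), Slfn5 (−1.97 ± 0.06), the adenylyl cyclase gene Adcy6 (−2.11 ± 0.07), Pdk1 (−1.74 ± 0.06) and Cbx6 (−1.83 ± 0.06; SE). Adrb1 stood at 0.695 ± 0.293 and 0.847 ± 0.231 CPM (SD, n = 4 each; adjusted p = 0.599). Treated library 2 stood apart from the other treated libraries on the second principal component (69.5, against −49.1 to −14.3). The CD4 T cell libraries come from a separate deposited table with no batch label.

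**Figure D3:**
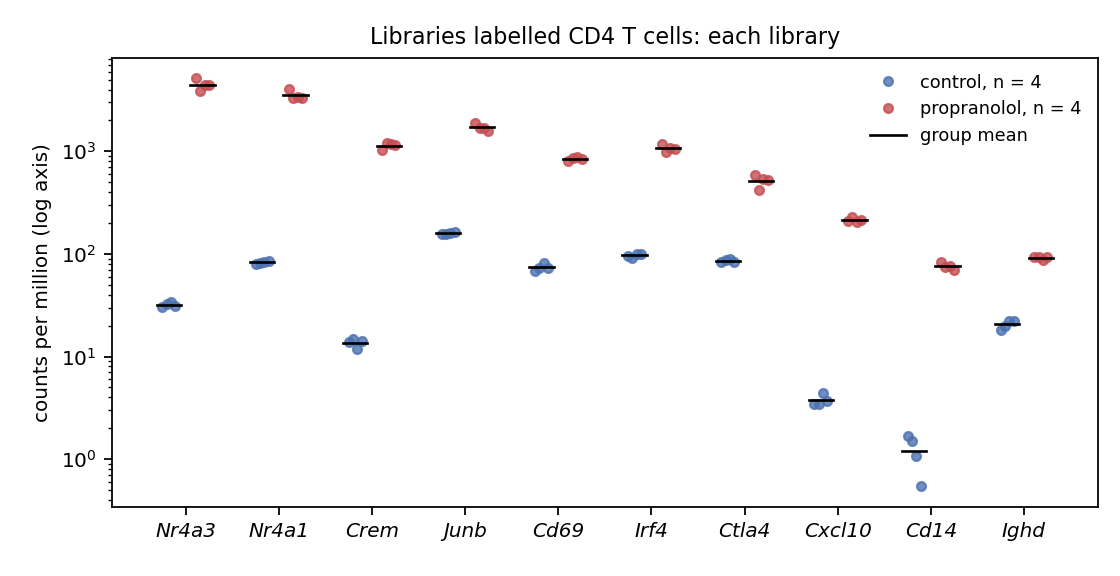
CPM (log axis, scaled libraries) of 10 genes in each library labelled CD4 T cells, with black bars at the group means. Nr4a3 rose from a mean of 32.1 to 4478 CPM, and Cd14 of myeloid cells from 1.21 to 76.5 CPM.

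The fourth comparison asked whether the change with propranolol differed between kinds of material. Adrb1 and Adrb3 were higher in whole lung and lower in the libraries labelled monocytes when each kind was fitted alone. Endothelium genes fell in the libraries labelled monocytes too (median −0.45), and which cells held the receptor transcripts was not tested. The monocyte changes kept their size in 1 fit with lung (log2 −0.88 and −0.93), where the spread is shared with the more variable lung libraries, but did not pass there (adjusted p = 0.0675 and 0.140). The lung changes did not pass with the melanocyte covariate (adjusted p = 0.485 and 0.496) or, for Adrb1, under the resident scaling (log2 0.46, adjusted p = 0.150). The differences of their log2 changes (monocyte minus lung, TMM scaling, no covariate) were −2.15 ± 0.40 and −2.71 ± 0.52 (SE, adjusted p = 2.65e-04 and 3.3e-04), and with lung scaled on resident markers −1.33 ± 0.32 and −1.86 ± 0.40 (SE, adjusted p = 0.00161 and 8.45e-04). Hsph1 fell in both, with a difference of 0.14 ± 0.16 (SE, adjusted p = 0.480) under TMM, while under the resident scaling it fell more in lung (adjusted p = 0.0113 for the difference). Melanocyte genes fell in lung and rose in the libraries labelled monocytes (median difference 2.47), and endothelium genes fell in those libraries and rose in lung under TMM (median difference −1.34). The lung median of endothelium was 0.25 with the melanocyte covariate (adjusted p = 0.0789) and 0.03 under the resident scaling, which these genes help to set and which gave median differences of 3.13 for melanocyte and −0.49 for endothelium genes. With an estimated correlation neither difference passed under TMM (adjusted p = 0.461 for each), and under the resident scaling that of endothelium did (adjusted p = 7.83e-04) and that of melanocyte genes did not (adjusted p = 0.670). The change differed for 11673 of 20328 genes (5115 with the monocyte change the more positive, 6558 the more negative; the former were 43.8%, and up to 54.6% with 1 library left out), and for 11892 under the resident scaling (9944 and 1948, 83.6%). Of 4303 genes called in both comparisons 1388 (32.3%) moved in the same direction. Both were higher for 842 genes, against 901 for independent lists, and both lower for 546, against 1080. These counts rest on the TMM directions in lung. Under the resident scaling 1792 of 3805 (47.1%) moved in the same direction, with 395 higher in both against 240 for independent lists and 1397 lower in both against 1775.

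Between libraries labelled CD4 T cells and those labelled monocytes, the largest list differences were in cAMP and CREB targets (median difference 3.15), neutrophil genes (2.91) and immediate early genes (2.41). The cAMP and immediate early differences also passed with an estimated correlation, the only 2 of 49 list differences tested that did. Fos and Nr4a1, members of these lists, started from unlike levels. In plain CPM Fos stood at 871 in untreated and 826 in treated libraries labelled monocytes, against 56.3 and 209 in those labelled CD4 T cells. Nr4a1 stood at 728 and 776, against 94.4 and 3062. The change differed for 9558 of 20023 genes. Of 3138 genes called in both, 1553 (49.5%) moved in the same direction, with 938 higher in both against 795 for independent lists and 615 lower in both against 658.

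**Figure D4:**
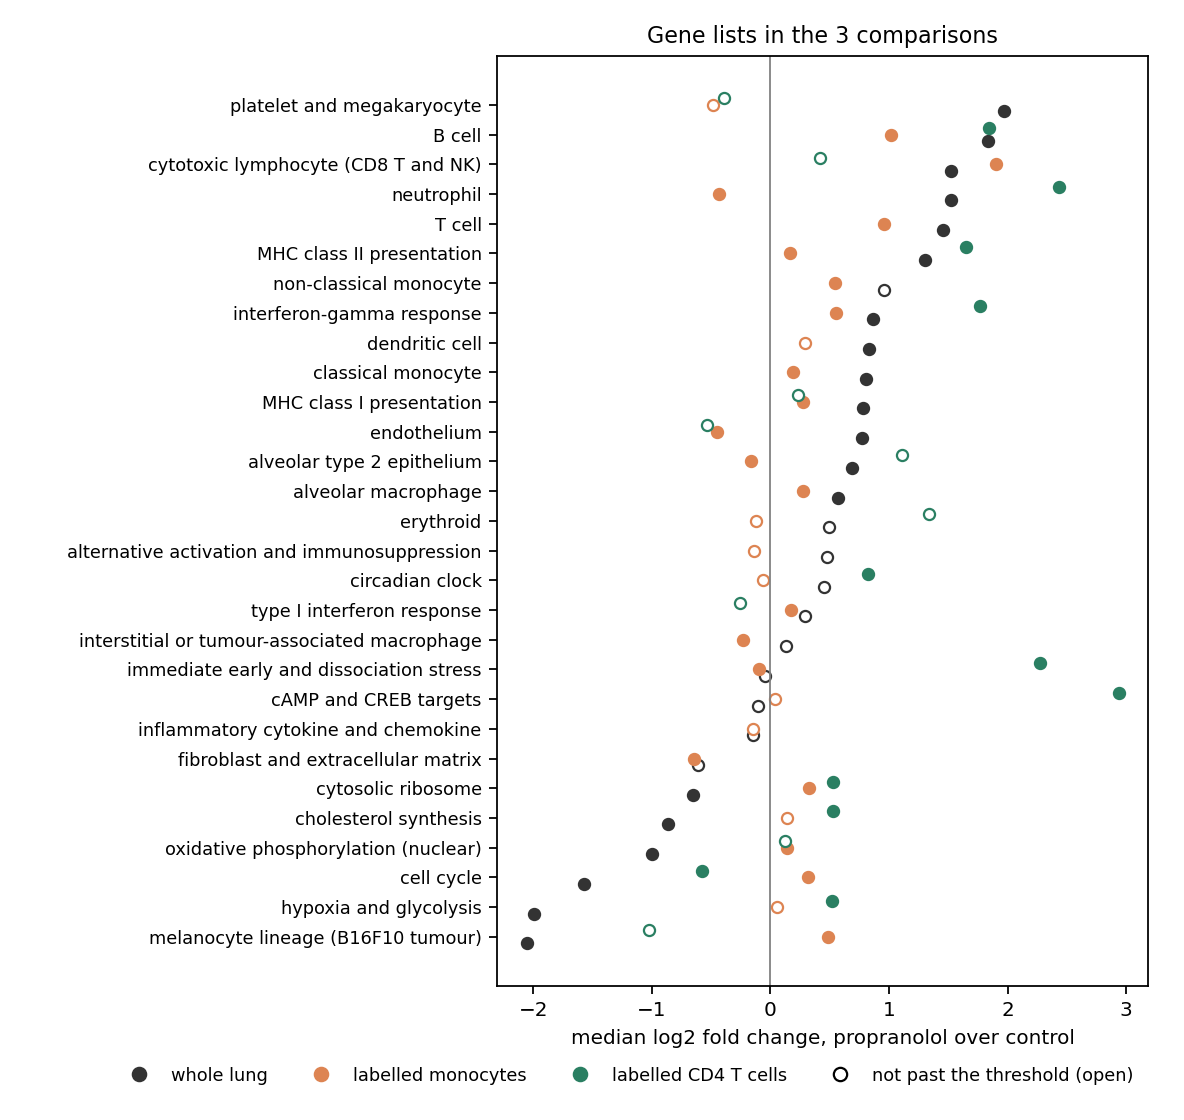
Median log2 fold change (propranolol over control) of the members of each gene list tested in whole lung and at least 1 other comparison, with filled circles for lists past the threshold with the preset correlation. The melanocyte list lies at −2.05 in whole lung and 0.49 in the libraries labelled monocytes, and the cAMP list at 2.94 in the libraries labelled CD4 T cells.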

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

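The interaction tests were planned; the test for a library far from the rest of its group was run on 372 values, each the values of a gene or list in 1 group. In 10 of them a library stood apart by more than Dixon's critical value, where chance gives about 5% of values. The ratio given is the gap to the nearest library over the whole range of the group. Untreated lung library 1 was lowest in Cr2 (2.01 CPM, others 2.34 to 2.45; ratio 0.748), and treated lung library 2 was highest in Trim30b (9.78 CPM, others 7.18 to 7.45; ratio 0.898). Among the libraries labelled monocytes, treated library 2 was lowest in Itgb7 (137 CPM, others 141 to 142; ratio 0.929) and untreated library 4 lowest in Adrb1 (67.0 CPM, others 73.2 to 73.6; ratio 0.939). Among those labelled CD4 T cells, treated library 1 was highest in Nr4a1 (4018 CPM, others 3307 to 3350; ratio 0.940) and untreated library 1 highest in Cdkn1a (3.22 CPM, others 2.68 to 2.69; ratio 0.988). In mean log2 CPM of a list, treated lung library 2 was highest in alternative activation (5.15, ratio 0.834), treated lung library 5 highest in cardiac muscle (1.49, others 0.68 to 0.83; ratio 0.820), untreated CD4 T cell library 1 lowest in neutrophil genes (2.75, others 3.14 to 3.16; ratio 0.938) and untreated CD4 T cell library 3 highest in endothelium genes (1.53, others 1.09 to 1.14; ratio 0.874).

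The change with propranolol differed between kinds of material for 3 of the 6 gene differences reported. Monocyte minus lung, the differences were −2.15 for Adrb1 and −2.71 for Adrb3. CD4 T cell minus monocyte, the difference was 1.16 for Adrb1 (adjusted p = 0.00226). In the CD4 T cell libraries Adrb1 was low (0.695 CPM untreated, 0.847 CPM treated) and its own change did not pass (adjusted p = 0.599). With lung scaled on resident markers, chosen after seeing the data, the monocyte minus lung differences of Hsph1 and Ighd passed too (adjusted p = 0.0113 and 0.0381), that of Ighd with its sign turned (0.45, against −0.41 under TMM). Of 49 list differences, 25 passed with the preset correlation and 2 of these with an estimated one.

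Monocyte minus lung, the median difference was above 0 for melanocyte genes (2.47), cell cycle (1.76), hypoxia and glycolysis (1.76), oxidative phosphorylation (0.99), cholesterol synthesis (0.87) and cytosolic ribosome (0.85). It was below 0 for platelets (−2.53), neutrophils (−2.13), endothelium (−1.34), MHC class II (−1.17), B cells (−0.99), alveolar type 2 cells (−0.94), dendritic cells (−0.79), classical monocytes (−0.73) and MHC class I (−0.46). With lung scaled on resident markers the median turned above 0 for MHC class I (0.41, adjusted p = 0.866), classical monocytes (0.13) and dendritic cells (0.04), the last 2 with a test direction still downward, and cAMP and CREB targets passed (1.06, adjusted p = 0.0403). CD4 T cell minus monocyte, it was above 0 for cAMP and CREB targets (3.15), neutrophils (2.91), immediate early genes (2.41), MHC class II (1.56), interferon-γ response (1.33), circadian clock (1.18), B cells (0.73) and hypoxia and glycolysis (0.48), and below 0 for cytotoxic lymphocytes (−1.11) and cell cycle (−0.92).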

How the results depend on the processing

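Alternatives chosen after seeing the data were the resident lung scaling, the summed monocyte libraries and the left-out libraries of the interaction fits. Under DESeq2 size factors, the DESeq2 test, limma-voom with and without quality weights and the changed filters, the count of changed genes in each of the 3 comparisons stayed within 1.5 times its reported value. The counts of genes whose change differs were run under the size factors and limma-voom with and without quality weights, and, for monocyte against lung, the resident lung scaling, and stayed within 1.5 times too. Under the first set of alternatives each named gene that could be tested kept its direction and its side of the threshold.

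With an estimated correlation the lists past the threshold went from 21 to 0 in lung, from 20 to 3 in the monocyte libraries and from 20 to 8 in the CD4 T cell libraries; with fry 25, 20 and 27 passed. With the melanocyte level as a covariate, 1498 lung genes changed in place of 13189, and 1441 of them were also called without it. Under it Dct (0.31), Mlana (0.20) and the melanocyte list (median 0.089) reversed, and the smooth muscle list shrank to a median of 0.076 with its test turned downward (adjusted p = 0.970); none of these passed; 9 more of the 30 named genes no longer passed, and the fibroblast (−1.06), cAMP (−0.45) and immediate early (−0.06) lists now passed (adjusted p = 2.54e-04, 0.00762 and 0.00901). The melanocyte genes make up the covariate, which fixes their own result. The covariate follows the groups closely, since treated lungs held less melanocyte RNA, so a lost call can come from that overlap. In the monocyte libraries 2069 genes changed in 1 fit with lung, where the spread is shared with the more variable lung libraries, and 10 of 30 named genes no longer passed; 1377 changed with the close libraries summed, a fit of fewer samples, and 4 no longer passed. Under the resident lung scaling 1 named gene, Adrb1, no longer passed in lung (0.46, adjusted p = 0.150).

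Replicate numbers gave no steady sign of pairing. In no comparison did every same-numbered pair correlate above 0.1 or every library correlate best with its own number. Lung numbers 1 and 3 correlated at 0.28 and 0.37, though each correlated better with another number. Number 1 of the CD4 T cell libraries correlated best with its own number. With so few libraries this check cannot exclude pairing. With a replicate block, 12998 genes changed in lung, 3544 in the monocyte libraries and 9579 in the CD4 T cell libraries, and 21, 21 and 20 lists, with platelet genes past the threshold in the monocyte libraries as the list added. The cause of the lower monocyte count was not tested.

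Leaving out each library in turn gave 12118 to 13439 genes in lung (13139 without untreated library 2, which lay apart on the second principal component), 4414 to 5113 in the monocyte libraries and 9122 to 10739 in the CD4 T cell libraries (the highest without treated library 2). The lists ranged from 21 to 23, 18 to 20 and 19 to 22, and the genes whose change differed from 10963 to 12186 (monocyte against lung) and 9020 to 10093 (CD4 T cell against monocyte). No named gene lost its call or direction in these fits. In the monocyte libraries the interstitial macrophage list no longer passed without untreated or treated libraries 1 or 2 (adjusted p = 0.0634 to 0.116), the neutrophil list without libraries 3 or 4 of either group (0.0768 to 0.147), and the type I interferon list without untreated library 3 or 4 (0.0610 and 0.0703). In the CD4 T cell libraries the naive list no longer passed without untreated library 4 (0.0509) and the hypoxia list without treated library 2 (0.0627). Lists that passed in such a fit but not with all libraries and the same test were, in lung, circadian clock without untreated library 2 (0.0441), non-classical monocyte without untreated 3 or treated 5 (the higher adjusted p was 0.0387) and type I interferon without untreated 4 (0.0334) or treated 5 (0.0253). In the monocyte libraries they were platelets without untreated 1 or 2 or treated 3 or 4 (0.00826 to 0.0482), and in the CD4 T cell libraries cytotoxic genes without treated 1, 3 or 4 (0.0330 to 0.0462) and erythroid genes without treated 1 (0.00888). Depth limits genes of low counts, such as Adrb1 in the CD4 T cell libraries.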

Other observations

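Tests chosen only after the results were seen were those of residual blood and of its white cells and platelets, of resident lung cells, of temperature (written first for lung and monocytes together, where it was not met because Rbm3 fell in lung, and then split), of carried-over cells, and the counts over other splits of the libraries; those of tumour RNA and of heat stress on the heat shock genes were written before their medians were seen. A list of 17 targets of heat shock factor (3 of them, Hspa1a, Hspa1b and Dnajb1, also in the immediate early list), the transcription factor of the heat shock response, was added after Hsph1 and Dnaja1 had come up among the lower genes, and leaves both out. In whole lung 15 of its 17 genes fell and none rose, with a median log2 change of −1.28. Hspa1b changed by −2.59 ± 0.31, Hspb1 by −2.35 ± 0.46 and Hsp90aa1 by −2.02 ± 0.26 (SE). In the libraries labelled monocytes 13 fell and none rose, with Hspb1 at −1.12 ± 0.06 and Hspa4l at −0.90 ± 0.05. In those labelled CD4 T cells 12 rose and 2 fell (median 0.38): Hspa1a rose by 4.37 ± 0.22 and Hspd1 fell by 0.44 ± 0.07 (SE).

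In the airway list of whole lung, described after its values were seen, members moved both ways. Under TMM scaling 8 rose, which were the club cell gene Scgb1a1 (log2 0.90 ± 0.33, adjusted p = 0.0316), Foxj1 (0.62 ± 0.26, adjusted p = 0.0478) and Dnah5 (1.04 ± 0.35, SE, adjusted p = 0.0192) of ciliated cells, and Ccdc153, Tppp3, Tmem212, Cfap126 and Dynlrb2. Scgb3a2 (0.06 ± 0.34) and Cyp2f2 (0.97 ± 0.46, SE) did not pass. Under the resident lung scaling none rose and 5 fell. The 4 that fell under TMM were Reg3g (−6.02 ± 0.87, SE), Muc5b (40.7 ± 23.1 CPM in untreated and 5.08 ± 0.953 CPM in treated lung), Scgb3a1 (17.3 ± 13.6 and 2.02 ± 1.38 CPM) and Bpifa1 (11.3 ± 12.4 and 0.495 ± 0.572 CPM; SD, n = 5 each).

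Heat shock genes were lower in whole lung and in the libraries labelled monocytes. Less tumour RNA would lower them where melanocyte genes fell. Their median also fell in the monocyte libraries, where melanocyte genes rose (−0.38, SE across members 0.07), which argues against less tumour RNA there. That fall is in other material and cannot decide the cause in lung. With the melanocyte level as a covariate 9 still fell in lung (median −0.72). A lower temperature of the tissue would raise the cold-induced genes Cirbp and Rbm3; in lung Cirbp rose by 0.92 but Rbm3 fell by 0.52 on the log2 scale, which argues against it there, though with the melanocyte level as a covariate Rbm3 was at 0.08 ± 0.10 (SE, adjusted p = 0.625). In the monocyte libraries both rose (the smaller change was 0.56), so a lower temperature remains a candidate explanation there, beside an effect of propranolol, which these data do not separate from it. Endothelium and fibroblast genes fell in the monocyte libraries too (medians −0.45 and −0.65), and whether the heat shock fall followed them was not tested. Other causes were not tested.

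Immune genes rose in whole lung. Less tumour RNA that raised every resident cell type alike would raise immune genes no more than resident lung genes. B cell, T cell, cytotoxic and MHC class II genes rose by 0.79 log2 more (exact permutation test, two-sided p = 0.00794, the smallest that 5 against 5 allows). These lists were chosen after the results were seen, and the p-value does not allow for that choice. Under the resident scaling, medians were near 0 for MHC class I (0.02), classical monocyte (0.05), dendritic cell (0.07) and interferon-γ genes (0.11), though 0.76 for neutrophil genes. The excess over resident genes was thus not shared by all immune lists. Residual whole blood was set to raise erythroid genes as much as the B cell, T cell, cytotoxic and MHC class II genes. The latter rose by 1.12 log2 more than erythroid genes (exact permutation test, two-sided p = 0.00794, erythroid median 0.49). The fold change from added blood depends on each gene's untreated level, so this test cannot exclude residual blood. Platelet genes rose by 0.99 log2 more than resident genes (exact permutation test, p = 0.00794), neutrophil genes had a median of 1.52, and the rise of immune minus platelet genes was −0.20 (p = 0.0794), so white cells and platelets of the blood held in the lungs stay open. More immune cells or a change within them may also contribute, a hypothesis found on these data, and whether they lay in vessels, tumour nodules or lung tissue was not tested.

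Activation genes rose in the libraries labelled CD4 T cells, together with B cell, myeloid and neutrophil markers. Carried-over cells alone were predicted to raise T cell activation genes no more than those markers. The genes used were Cd40lg, Il2, Icos, Tnfrsf4, Tnfrsf9 and Ctla4, which also stand in part in the activated T cell list. They rose by 0.90 log2 more than the mean of those markers (exact permutation test, two-sided p = 0.0286, the smallest that 4 against 4 allows). The fold change from carried-over cells depends on each gene's untreated level. A mean over markers therefore sets no upper bound, and this test cannot exclude carried-over cells. Heat stress during preparation was set to give a heat shock median above 1; it was 0.38 with an SE across members of 0.34, and Hspa1a and Hspa1b rose steeply, so stress in handling and activation in the animal cannot be told apart for these genes. No batch label allows a test of a separate preparation of the groups. An effect of the drug and one of handling may both contribute.

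Other splits of the libraries tested whether chance could give the counts. For genes, with each library counted as independent, chance was excluded in lung (13189, highest of the other splits 0, 1 of 100 splits as large). On the same terms it was excluded in the CD4 T cell libraries (9929, highest other 0, 1 of 35). Untreated CD4 T cell pairs, however, had a chi-square per gene of 4.86 to 7.04, and treated libraries 3 and 4 one of 5.50. The close monocyte pairs lay at 3.52 to 5.28, so independence is uncertain for the CD4 T cell libraries too. In the monocyte libraries 1 of 35 splits was as large (5553; highest other 209), which counts each library as independent. That highest other split joins untreated libraries 1 and 2 with treated libraries 3 and 4 and so follows the close pairs. Splits that keep those pairs together number 3, too few for a share under 0.05 (5553; highest other 209). For the counts of lists, chance was not excluded in lung (21, highest other 29, 51 of 100 as large) or in the monocyte libraries (20, highest other 21, 2 of 35). Only with each library counted as independent was it excluded in the CD4 T cell libraries (20, highest other 18, 1 of 35). For the genes whose change differs, the splits shuffled both kinds of material at once, with each library counted as independent. For monocyte against lung 1 of 50 was as large (11673, highest other 10242, a split that keeps the lung groups as they are). For CD4 T cell against monocyte 1 of 50 was as large (9558, highest other 7969, a split that keeps the CD4 T cell groups). Such shuffling removes the change in each kind, so these splits cannot tell whether the 2 changes differ.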
